A study of Homo sapiens with 3 samples.

How the data were processed

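Gene expression was measured on Affymetrix arrays in LNCaP cells, an established human cell line derived from a prostate carcinoma metastasis that responds to androgens. Per the labels' protocols, the cells were grown in RPMI1640 with serum, transfected with siRNA using RNAiMAX and harvested after 72 hours, total RNA was extracted with Trizol, and biotin-labelled target was made with a whole-transcript kit. The series holds 3 arrays: 1 with a negative control siRNA and 2 with siRNAs against the SLC45A3-ELK4 chimeric transcript, titled siSE1 and siSE2. On the array titled siSE2, the transfection field of the labels names siSE1, while its title, source name and description name siSE2. The title was followed. Either reading places the array in the same group, the chimera siRNA group (n = 2), which was compared with the control group (n = 1). If the transfection field is right, both arrays carry siSE1, and comparisons of the siRNAs below would be between repeats of 1 siRNA. The labels do not say whether the 3 arrays came from separately grown cultures, so p-values measure the spread between these arrays only, which may be technical.

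The authors deposited 1 table of 33297 probe set rows with 1 column per array. The authors made the deposited log2 values with Affymetrix Expression Console, per the submitters' processing notes, which give no version or algorithm. The values were taken to be on the log2 scale from their range, 1.43 to 13.9, and from array medians of 5.80 (control), 5.84 (siSE1) and 5.84 (siSE2), because the scale is not stated in the sources used here. The background correction and the genome build are not given in the sources used here. A platform annotation named 1 gene for 19460 probe sets and several genes for 1754, and 12083 probe sets were unnamed in it. Of the 19460 probe sets, 19429 matched a human gene table of another build (used for names only) by gene identifier. Some well known genes are not analysed here because no probe set named them alone.

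Probe sets of 1 gene were averaged (769 genes had more than 1), which gave 18417 genes. The 5525 genes whose mean over the 3 arrays lay below the 30th percentile (log2 5.12) were left out, and 12892 genes were tested. The siRNA arrays were compared with the control array by limma 3.58.1 (lmFit and eBayes, in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. This fit has 1 residual degree of freedom, which comes from the difference between the siRNA arrays, so the lone control array is assumed to vary as they do. Errors given as SE are the moderated standard errors of this fit. In parallel, genes at least 1.5-fold from the control in the same direction on both siRNA arrays were counted, with no test. The number of arrays limits the precision.

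The fit was tested on simulated data: in 12892 simulated genes compared as here, 96 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were recovered. Over 20 such runs 13.0% of the calls were false, against 5.28% when the true prior was supplied to the fit. The prior degrees of freedom, estimated from single residuals, ran from 6.65 to infinity in these runs, where the simulated value was 8.46. Among 20 simulated sets with no changed gene, 8 gave calls, at most 37.

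A total of 24 gene lists, all with at least 5 tested members, were tested with camera. The test was two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. It was run again with an estimated correlation, which leaves the camera test 1 degree of freedom. A list can hardly pass on 1 degree of freedom, so failing there cannot decide whether a call holds. With fry, which tests whether a list's genes move on balance in 1 direction, no list had an adjusted p under 0.05. Each list's median was also set against 10000 random lists of the same size matched on mean expression. In a simulated dataset with the replication list shifted by -0.4 on the log2 scale, camera called that list and 0 others. The simulated genes were independent, so this does not show how often camera calls lists of correlated genes. Covariance of the 2 siRNAs' changes was set against the value that a shared control gives, the variance of siSE1 minus siSE2 divided by 2, and against 100 simulated datasets without effects.

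The groups, lists, tests, filters and the rule for named genes were fixed before the data were examined. The genes named are SLC45A3 and ELK4; the 12 genes higher and the 12 lower with the largest smaller one of their 2 changes, in the same direction with both siRNAs; and from each list up to 4 members in the same order. Genes outside this rule are marked as chosen after their values were seen. Alternatives covered 3 normalizations (quantile, equal array medians, cyclic loess), no filter and a filter at the 50th percentile, the highest probe set per gene, other variance priors, other thresholds, an estimated correlation and leaving out each siRNA array. While names of list members were matched, synonyms shared by several genes were dropped after the list results had been seen; this took 1 gene from the androgen receptor-repressed list and 1 from the histone list and changed no list's call.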

Results

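LNCaP prostate cancer cells were profiled 72 hours after transfection with a negative control siRNA (1 array) or with siRNAs named siSE1 and siSE2 (1 array each). Both siRNAs were directed against SLC45A3-ELK4, a chimeric transcript that joins sequence of the neighbouring genes SLC45A3, which encodes a prostate-enriched membrane transporter, and ELK4, which encodes an ETS-family partner of serum response factor. The comparison asks which genes change when this transcript is targeted. Across the 33297 deposited log2 values the Pearson correlation was 0.993 between siSE1 and siSE2, 0.989 between the control and siSE1 and 0.991 between the control and siSE2. No pair of arrays held more than 131 identical values.

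The parent genes were examined first. SLC45A3 read 9.66 on the control array, 9.14 with siSE1 and 9.27 with siSE2 (log2), a mean difference of -0.46 ± 0.15 (SE, n = 2 against 1) that did not pass the test over all genes (limma, adjusted p = 0.154). Its unadjusted interval, from -0.78 to -0.13, excluded 0 (limma, unadjusted p = 0.0114). ELK4 read 8.50 on the control array, 8.45 with siSE1 and 8.20 with siSE2, a difference of -0.18 ± 0.16 (SE; limma, adjusted p = 0.582). The unadjusted interval of the ELK4 difference ran from -0.53 to 0.17. The probe sets report whole parent genes, and the values do not resolve the chimeric junction, so they do not check the knockdown itself. Among the 9 tested genes at or near this locus 0 passed the test over all genes, and 1 did when adjusted over the list alone. KLHDC8A differed by 0.55 ± 0.14, RAB29 by -0.28 ± 0.15 and NUCKS1 by 0.13 ± 0.14. KLHDC8A was dim, with 4.78 on the control array, 5.31 with siSE1 and 5.34 with siSE2, near the filter level of 5.12. The list's median was 0.0057, while its mean was -0.035 and its test pointed lower (camera, adjusted p = 0.905), and the medians were -0.057 with siSE1 and -0.12 with siSE2.

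By the mean of the siRNAs, ATOH1 had the largest change upward among the genes tested and the growth factor gene IGF1 the largest downward. ATOH1, a transcription factor of secretory and sensory cell fates, rose 4.66-fold (log2 2.22 ± 0.15, SE; limma, adjusted p = 0.00124). CDKN1A, which encodes the CDK inhibitor p21, rose 2.58-fold (1.37 ± 0.15; adjusted p = 0.0147). IGF1 fell 3.60-fold (-1.85 ± 0.17; adjusted p = 0.00774). Of 12892 genes tested, 32 rose and 92 fell, all 124 in the same direction with both siRNAs. A gene with opposite changes could hardly pass, since the fit takes its spread from the difference between the siRNA arrays. The size rule, at least 1.5-fold with both siRNAs, was met by 75 genes higher and 197 lower, which include every gene that passed the test. These calls rest on 1 residual degree of freedom: with no filter on dim genes ATOH1 alone passed, the other genes said here to have risen or fallen having adjusted p from 0.0927 to 0.136, and with a filter at the 50th percentile 15 genes rose and 20 fell (42.9% higher, against 25.8%). On simulated data 13.0% of calls were false, above the nominal threshold. Those data had equal noise on the 3 arrays, so a noisier control array could add false calls. At an unadjusted p under 0.05, 833 genes were higher and 1458 lower.

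Among the 12 higher genes that ranked first by the smaller of their changes with siSE1 and siSE2, 11 rose. OR51E1, an olfactory receptor expressed in prostate, rose 2.87-fold (log2 1.52 ± 0.17), from 5.16 on the control array, near the lower limit of the genes tested (5.12). REG4, a secreted lectin of the gut, rose 2.74-fold (1.46 ± 0.18). TP53INP1, a p53-induced gene, and CLDN12, a tight junction claudin, both rose 2.30-fold. TOMM22, a receptor for protein import into mitochondria, rose by 1.13 on the log2 scale. SF3B5, a spliceosome subunit, rose 2.14-fold, and PCTP, a phosphatidylcholine transfer protein, 2.13-fold. The small nucleolar RNA gene SNORA14A rose 2.09-fold and DUSP4, a MAP kinase phosphatase, 2.06-fold. SLPI, a secreted protease inhibitor, read 7.87 on the control array, 8.99 with siSE1 and 10.08 with siSE2, and its mean difference of 1.66 ± 0.34 did not pass (limma, adjusted p = 0.0569), though it did with quantile normalization (adjusted p = 0.0293).

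Among the 12 lower genes that ranked first by the smaller of their changes, 11 fell. S100A10, the partner of annexin A2, fell 2.72-fold (log2 -1.45 ± 0.17), and TMT1A, a thiol methyltransferase, fell 2.49-fold (-1.32 ± 0.14). RTKN2 fell 2.46-fold, GINS4, a subunit of the replicative helicase, 2.22-fold, and ACADL, a mitochondrial acyl-CoA dehydrogenase, 2.22-fold. MYBL1, a MYB-family transcription factor, fell 2.16-fold, GDPD3 2.14-fold, the histone gene H2AC20 2.10-fold, GCG, which encodes proglucagon, 2.08-fold, and the sulfate transporter gene SLC26A2 2.05-fold. GCG read 6.04 on the control array and 4.99 and 4.97 with the siRNAs, near the lower limit of the genes tested (5.12). SPIC, an ETS-family factor, read 6.59, 4.23 and 5.56, and its difference of -1.70 ± 0.40 did not pass (limma, adjusted p = 0.0788), though it did with equal array medians (adjusted p = 0.0429).

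**Figure D1:**
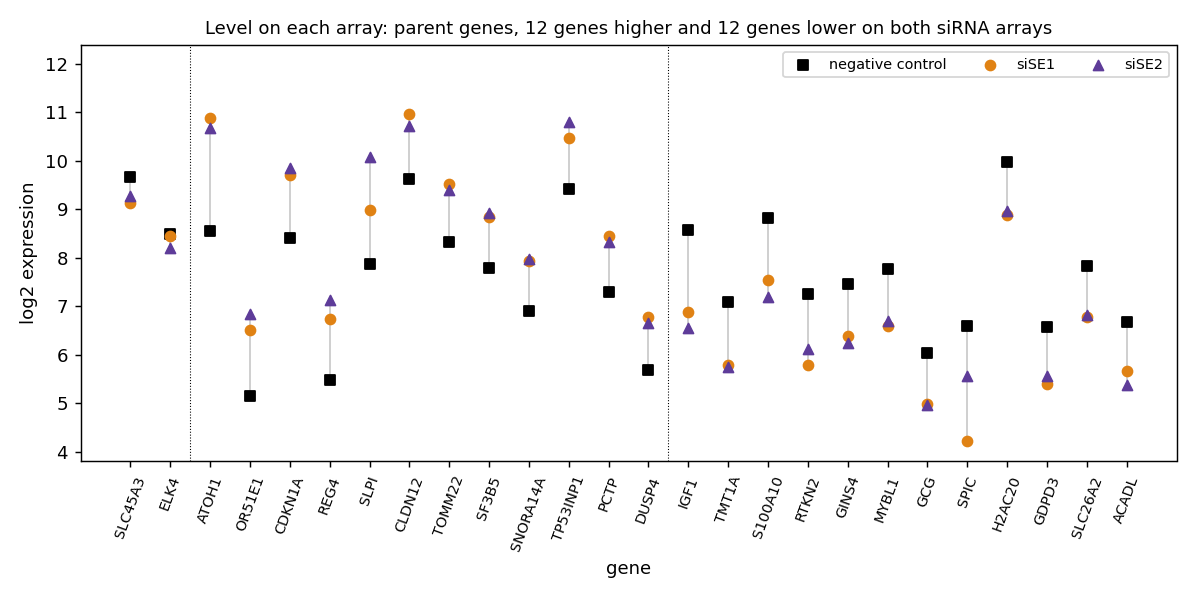
Log2 expression (vertical axis) of SLC45A3 and ELK4 and of the 12 higher and the 12 lower genes that ranked first by the smaller of their changes with the siRNAs (horizontal axis), 1 point per array (square, control; circle, siSE1; triangle, siSE2; grey lines join the lowest and highest array). ATOH1 read 8.56 on the control array, 10.90 with siSE1 and 10.67 with siSE2, and among the genes plotted SPIC and SLPI show the widest gaps between the siRNAs.

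The siRNAs gave similar changes across genes. The Pearson correlation of their log2 fold changes over 12892 genes was 0.754 (Spearman 0.741; genes are not independent replicates). Unchanged arrays that share 1 control gave a correlation of 0.500 in 100 simulations, with a range of 0.482 to 0.518. The simulated genes were independent, so this range leaves out noise that correlated genes share. The same holds for the simulated counts below. The simulations also give the control array the same noise as the siRNA arrays, which fixes their correlation near 0.500. In the 5525 dim genes below the filter the observed correlation was 0.600, so a noisier control array is not excluded. Over the 12892 genes tested the covariance was 0.0623. The shared control accounts for 0.0208 of it if that array varies as the siRNA arrays do, leaving a difference of 0.0415. With siSE1 187 genes were at least 1.5-fold higher and 551 lower, and with siSE2 155 and 364. The 75 genes shared among those higher compare with 2.25 for independent lists and with a mean of 10.6 in simulations without effects. The 197 shared among those lower compare with 15.6 and 9.28. The lone control array could not be split, so part of the excess may come from it. No gene was past 1.5-fold in opposite directions with the siRNAs.

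Some genes stood apart between the siRNAs, which has no test with 1 array each. They differed by at least 1.5-fold for 149 genes, 52 higher with siSE1 and 97 higher with siSE2, and by at least 2-fold for 14. The following genes were chosen from these 14 after their values were seen. GINS1, another helicase subunit, read 9.61 on the control array, 7.56 with siSE1 and 9.05 with siSE2. SPOPL, an adaptor of ubiquitin ligases, read 6.60, 5.34 and 6.91, and OSMR, the oncostatin M receptor gene, 7.53, 6.53 and 7.54 in the same order. THBS1, which encodes thrombospondin, read 8.25, 8.50 and 7.34, and CCL20, a chemokine gene, 6.44, 7.15 and 6.09.

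**Figure D2:**
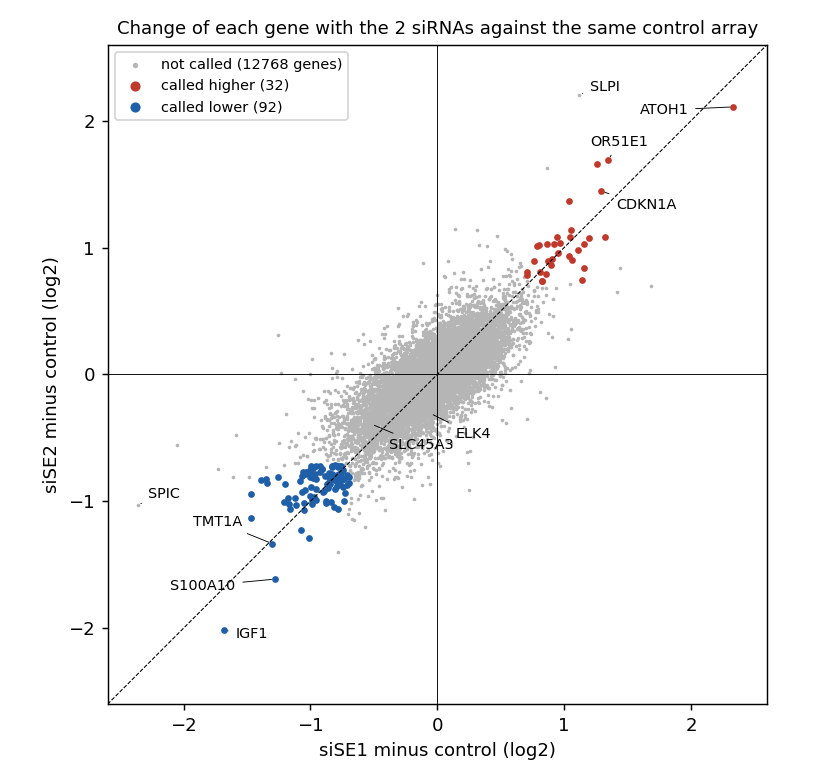
Log2 fold change of each of 12892 genes with siSE1 (horizontal axis) and with siSE2 (vertical axis) against the same control array; red and blue points are the 32 genes that rose and the 92 that fell by limma, and the dashed line marks equal change. The shared control alone stretches the cloud along the dashed line (simulated correlation 0.500 with equal noise on the arrays, observed 0.754).

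Genes of DNA replication and of mitosis stood lower together on both siRNA arrays. The median of the 47 tested replication and G1/S genes was -0.44 (log2), with -0.51 for siSE1 and -0.41 for siSE2. Of these genes 7 fell, 0 rose and 40 did not pass; adjusted over the list alone, 30 fell and 1 rose. GINS4, RFC5, RFC4 and GINS3, subunits of the replicative helicase and of the clamp loader, fell, with log2 changes of -1.15, -0.98, -0.89 and -0.85. The median of the 51 mitosis genes was -0.43, with 3 fallen, 0 risen and 48 not passing; adjusted over the list alone, 30 fell and 0 rose. KIF14, a mitotic kinesin, and the kinase genes PBK and MELK fell, with log2 changes of -0.90, -0.82 and -0.75. CENPI, a centromere protein gene, differed by -0.90 ± 0.20 without passing. Replication-dependent histone genes had a median of -0.29 over 30 genes, of which 4 fell, 0 rose and 26 did not pass (11 fell over the list alone). H2AC20, H2AC6, H4C5 and H3C2 fell, with log2 changes of -1.07, -1.03, -0.83 and -0.82. Histone genes are near-identical copies, so the signal of single members is uncertain. GINS3, KIF14, PBK, MELK, H2AC6, H4C5 and H3C2 did not pass with the filter at the 50th percentile (limma, adjusted p from 0.0503 to 0.0559). By camera with the preset correlation, the adjusted p was 3.4e-16 for replication, 7.5e-16 for mitosis and 2.5e-05 for histones. The estimated inter-gene correlations were 0.056, 0.46 and 0.13 in the same order. All lay above the preset value, so these p-values may be far too small, most of all for mitosis. Each median lay below all 10000 matched random lists. Those lists were matched on mean expression only, so they leave out this correlation too. With an estimated correlation none of the 3 lists passed (camera, adjusted p = 0.569 for each). That test has 1 degree of freedom, on which a list can hardly pass, so it cannot decide whether the calls hold. The same limit applies to the estimated-correlation values given for the lists below.

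The p53 targets stood higher as a list, with CDKN1A at their head. Of 27 tested members 3 rose, 0 fell and 24 did not pass; over the list alone 4 rose. CDKN1A, TP53INP1 and PLK2, a polo-like kinase induced by stress, rose by 1.37, 1.20 and 0.90 on the log2 scale, and GDF15, a stress-induced cytokine, differed by 0.67 ± 0.14. The list's median was 0.12 (camera with the preset correlation, adjusted p = 0.00417; adjusted p = 0.569 with an estimated correlation), above 99.9% of matched random lists. Among 13 CDK inhibitors and RB family genes CDKN1A alone rose, and the list did not pass (median 0.13; camera, adjusted p = 0.106). CDKN2B differed by 0.43 ± 0.14, and CCNG2 by 0.59 ± 0.20, with 0.34 for siSE1 and 0.83 for siSE2. The 35 immediate early and serum response factor targets had a median of 0.11 (camera with the preset correlation, adjusted p = 0.0291; adjusted p = 0.569 with an estimated correlation), and their call was lost with no filter (adjusted p = 0.0639). Of their members DUSP4 alone rose, by 1.04, and 0 fell, both over all genes and over the list alone; DUSP1, PHLDA1 and KLF4 differed by 0.56 ± 0.14, -0.47 ± 0.14 and 0.52 ± 0.15. The 26 apoptosis regulators did not pass as a list (median 0.05, with 0.08 for siSE1 and 0.07 for siSE2; camera, adjusted p = 0.114), and none passed singly; XIAP and MCL1 differed by 0.44 ± 0.14 and 0.41 ± 0.14.

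Androgen receptor targets stood lower as a list. The median of the 30 tested targets, SLC45A3 among them, was -0.25, at percentile 0.01 of matched random lists (camera with the preset correlation, adjusted p = 0.0217; adjusted p = 0.569 with an estimated correlation). ELL2, a transcription elongation factor gene, alone fell (log2 change of -0.79; limma, adjusted p = 0.0398, and 0.0512 with the filter at the 50th percentile), and 0 rose; over the list alone 1 fell and 1 rose. ACP3, which encodes prostatic acid phosphatase, went the other way, by 0.76 ± 0.15 (limma, adjusted p = 0.0569 over all genes). TMEM79 differed by -0.57 ± 0.17. Of the 9 tested genes known to be repressed by the receptor 0 passed over all genes, while 5 rose and 1 fell over the list alone; their median was 0.37 (camera, adjusted p = 0.0599). CAMK2N1 differed by 0.76 ± 0.19 and PEG10, a retrotransposon-derived gene, by -0.85 ± 0.19. Luminal epithelial markers did not pass (camera, adjusted p = 0.803), with a median of 0.021 and a mean of -0.0067, opposite in sign, and medians of -0.049 with siSE1 and -0.018 with siSE2. The keratin genes KRT8 and KRT18 differed by 0.43 ± 0.14 and 0.42 ± 0.15, and KLK3, which encodes prostate-specific antigen, by -0.39 ± 0.14. None of these markers passed, also adjusted over the list alone.

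Oxidative phosphorylation and cholesterol genes stood slightly lower as lists. Their medians lay at percentiles 0.24 and 1.79 of matched random lists. The oxidative phosphorylation median lay at percentile 6.05 with siSE1 and 0.02 with siSE2. Oxidative phosphorylation genes had a median of -0.18 over 36 genes (camera with the preset correlation, adjusted p = 0.00136; adjusted p = 0.569 with an estimated correlation), none passing over all genes and 5 falling over the list alone; COX7B, a cytochrome c oxidase subunit gene, differed by -0.71 ± 0.14. Cholesterol and SREBP genes had a median of -0.18 over 25 genes (adjusted p = 0.00676; adjusted p = 0.569 with an estimated correlation), none passing singly; FADS1, a fatty acid desaturase gene, differed by -0.46 ± 0.14. Of 34 unfolded protein response and ATF4 targets SLC7A5, an amino acid transporter gene, alone fell over all genes (log2 change of -0.88) and 3 fell over the list alone; HSPA5, an endoplasmic reticulum chaperone gene, differed by -0.63 ± 0.14. The list did not pass (median -0.04, with -0.08 for siSE1 and -0.05 for siSE2; camera, adjusted p = 0.680). Ribosomal protein genes (median -0.07, adjusted p = 0.263) and hypoxia and glycolysis genes (median 0.07, with 0.11 for siSE1 and 0.05 for siSE2, adjusted p = 0.161) did not pass, and none of their members did, also adjusted over the list alone.

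Interferon-stimulated genes did not stand higher on the siRNA arrays. The 18 tested members had a median of -0.06 (camera, adjusted p = 0.504), and of -0.07 with siSE1 and -0.13 with siSE2, with PARP14 and OAS3 at -0.56 ± 0.14 each, PARP9 at -0.55 ± 0.14 and ISG20 at 0.42 ± 0.14, and none passed over all genes (3 fell over the list alone). NF-kB inflammatory genes had a median of 0.16 (adjusted p = 0.161), with 0.32 for siSE1 and 0.09 for siSE2, and RNA interference genes -0.14 (adjusted p = 0.405), with AGO2 at -0.43 ± 0.14. ETS factors and their partners had a median of -0.15 (adjusted p = 0.725), with -0.057 for siSE1 and -0.11 for siSE2. Neuroendocrine markers had a median of 0.17 (adjusted p = 0.476), with 0.30 for siSE1 and 0.0040 for siSE2. No member of these 4 lists passed over all genes, and adjusted over the list alone 1 neuroendocrine marker fell. Markers of other cell types did not pass by camera: basal epithelial (median 0.10 over 6 genes, adjusted p = 0.680, with 0.12 for siSE1 and 0.06 for siSE2), fibroblast and stromal (0.08 over 11, adjusted p = 0.476, with 0.06 and 0.03) and blood cell markers (0.27 over 5, adjusted p = 0.0707). Adjusted over the list alone, 1 basal marker fell and 1 blood cell marker rose. LYZ, which encodes lysozyme, read 4.41 on the control array, 6.09 with siSE1 and 5.11 with siSE2, without passing over all genes (limma, adjusted p = 0.0989).

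**Figure D3:**
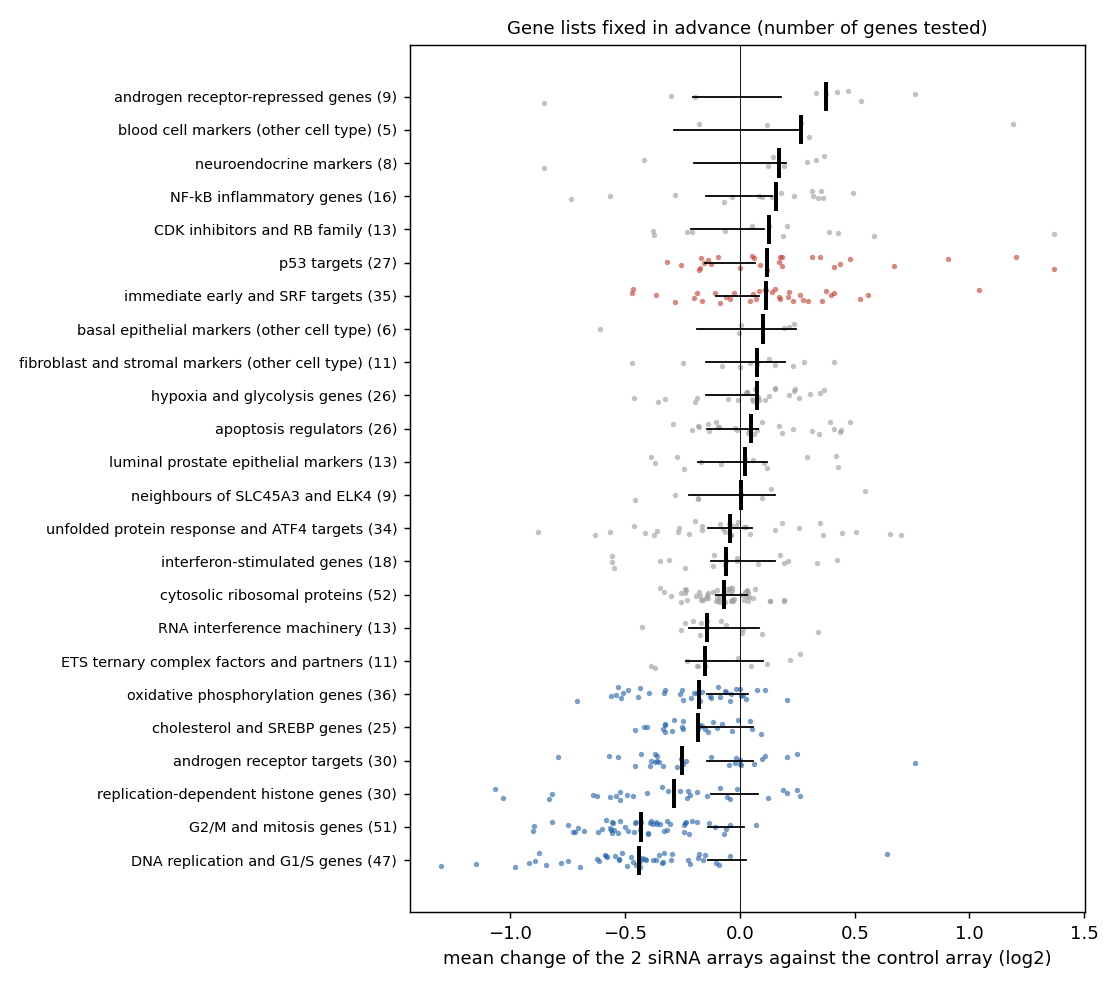
Mean log2 fold change of the siRNA arrays against the control array (horizontal axis) for the tested genes of 24 gene lists fixed in advance (vertical axis, number of genes in brackets); points are genes, thick bars list medians and thin lines the central 95% of medians of matched random lists. Blue and red mark lists lower and higher by camera with the preset correlation, grey the rest; replication and mitosis genes lie lowest, with medians of -0.44 and -0.43.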

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

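Probe sets outside the gene-level comparison also differed between the siRNA arrays and the control array, which drew attention because no comparison used them. Among 5349 probe sets above the filter level that the annotation does not list, 123 were at least 1.5-fold higher on both siRNA arrays and 87 at least 1.5-fold lower. These are 2.30% and 1.63% of such probe sets, against 0.582% and 1.53% of the genes tested. The first shares count single probe sets and the second genes, some of them averaged over several probe sets, so they are not strictly alike. What the unlisted probe sets measure is not given. Among 1318 probe sets that name several genes, 9 were higher and 10 lower by the same rule. These values have no test and no explanation was tested for them.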

How the results depend on the processing

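The prior degrees of freedom at their lowest simulated estimate, the p53 list without CDKN1A, the covariance in dim genes and the estimated correlations under other settings were chosen after the data were seen. Agreement of the siRNAs was judged against fixed tolerances, not a replicate SD. The count of genes passing limma (32 higher, 92 lower) moved most: 1 and 0 with no filter, 15 and 20 with a filter at the 50th percentile, 79 and 185 with equal array medians, 143 and 364 at an adjusted p under 0.1, and 1 and 0 with the lowest simulated prior. The higher count was 63 with quantile normalization and 52 with a trended prior. The prior degrees of freedom were estimated at 8.46, at 6.30 with no filter and at 10.5 with equal array medians. All 124 genes passed under quantile normalization, 121 under cyclic loess and 35 with the filter at the 50th percentile. ATOH1 passed under each of these, including no filter (adjusted p = 0.0252) and the lowest prior (0.0112). The size counts (75 and 197) became 11 and 13 at 2-fold and 136 and 349 for the mean of the siRNAs. Leaving out 1 siRNA array gave 155 to 187 genes higher and 364 to 551 lower, with no test, since 1 array against 1 leaves no residual degrees of freedom. The limma counts, the correlation and the list tests could not be computed there. With an estimated correlation 0 of the 8 lists called by camera passed, 0 had an unadjusted p under 0.05 and fry called 0. That camera test has 1 degree of freedom, and its smallest unadjusted p over all lists was 0.116, so it cannot decide whether the calls hold. The estimated correlation was above the preset 0.01 for replication, mitosis and histone genes and below it for the other called lists. Lists kept their direction elsewhere except 2 with no call. The median of the locus list became -0.0493 with quantile normalization, -0.0644 with cyclic loess, -0.182 with the filter at the 50th percentile and -0.116 to -0.0574 with 1 siRNA. Likewise the luminal median became -0.00102, -0.00907 and -0.0818, -0.0680 with the highest probe set per gene, and -0.0493 to -0.0178 with 1 siRNA; the cause was not tested. With the filter at the 50th percentile 4 more lists passed camera: androgen receptor-repressed genes (adjusted p = 0.0230), apoptosis regulators (0.0230), CDK inhibitors (0.0316) and hypoxia genes (0.0460). None passed there with an estimated correlation (camera, adjusted p = 0.534, and 0.600 for hypoxia genes), again on 1 degree of freedom, which cannot decide. The p53 list without CDKN1A had a median of 0.10 (camera, adjusted p = 0.0190; adjusted p = 0.569 with an estimated correlation). In the dim genes below the filter the correlation of the siRNAs was 0.600 and the covariance beyond the shared control 0.0114. SLC45A3 and ELK4 kept their direction and did not pass under any alternative with a test (adjusted p from 0.140 to 0.249 for SLC45A3). No gene named under the rule fixed beforehand changed sign. Of those that did not pass, SLPI, SPIC, ACP3, COX7B, GDF15, PEG10, CENPI and HSPA5 passed under at least 1 other normalization, probe set rule or prior. The genes picked because the siRNAs differed were not run under the alternatives, and SPOPL, OSMR, THBS1 and CCL20 lay on opposite sides of the control with siSE1 and siSE2. No paired analysis was possible because the control group holds 1 array. Pseudocounts do not apply to log2 values.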

Other observations

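The tests on the interferon response, on matched random lists for the cell cycle lists and on the splits of the arrays were chosen after the result was seen; so was the count of androgen receptor targets below SLC45A3. The secretory list was prompted by ATOH1 and REG4, and its 3 comparison lists were added after its result was seen. The genes in this paragraph were chosen after their values were seen. The enteroendocrine transcription factor gene NEUROG3 rose from 5.08 on the control array, near the level of the filter, to 6.15 and 5.98, and HEPACAM2, a gene of gut secretory cells, from 5.20 to 6.17 and 6.24. GCG and TTR fell, with log2 changes of -1.06 and -0.92. Of the 29 androgen receptor targets tested besides SLC45A3, 3 lay at or below its change.

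The first pattern is the set of 124 genes that passed limma. Setting siSE1 or siSE2 apart in place of the control array gave 0 genes by limma (459 and 154 at an unadjusted p under 0.05, against 2291), so 1 of the 3 splits gave a count as large, and 3 splits are too few for a share under 0.05. An intensity trend between arrays is argued against, since 97.6% of the genes still passed after cyclic loess. A measurement error of the control array as a whole stays open. The covariance over that of a shared control was 1.496 in 5525 dim genes (bootstrap interval over genes, 1.36 to 1.63), against 2.99 (2.84 to 3.15) in the genes tested. These intervals resample genes of the same 3 arrays, so they do not cover differences between arrays. The excess was smaller in dim genes but not below the bound, which was set before this result but after other results were seen. With 1 control array, the effect of the siRNAs and a culture that differed for another reason cannot be told apart.

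The second pattern is the lower level of replication, mitosis and histone genes beside higher CDKN1A, consistent with fewer cycling cells, which was not measured. An innate interferon response to siRNA was not seen in the 18 interferon-stimulated genes tested, where the higher of the medians was -0.068 (-0.21 to 0.075 at 2 SDs of random lists). It is not excluded, since the other members of the list of 40 were too dim to test. The control array also received an siRNA, so a response shared with it would cancel. A general drop of genes at that expression level is argued against, since the pooled median of 128 genes was -0.43 and 10000 matched random lists ran from -0.15 to 0.039. Each list alone had already lain below all its matched random lists, so pooling them was not an independent test. An effect of the targeted transcript, off-target effects and a difference in cell density between cultures stay open and were not tested. The off-target effects could be common to the siRNAs, or those of siSE1 alone if both arrays carry it.

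The third pattern is the rise of ATOH1 and REG4, for which a gut-like secretory programme is a hypothesis. In 28 other secretory genes, listed before their result as a list was seen, the median was 0.29, above all 10000 matched random lists (highest 0.20). Of these genes 20 were higher and 2 lower with both siRNAs, and none passed limma singly. The 2 lower genes were SPDEF, the lowest of the 28, and FOXA3, with mean log2 changes of -0.37 and -0.095. Some of the higher genes were dim: DLL4 and MUC4 each read 5.04 on the control array, below the filter level of 5.12. Of the brightest members on the control array, SOX4 and ST6GALNAC1 differed by 0.52 and 0.58. The others, STARD10, GALNT7, CREB3L4 and RAB26 besides SPDEF, differed by 0.014, 0.13, -0.044 and 0.071. The rise was thus not even across expression levels. NEUROG3 and HEPACAM2, which rose, and GCG, which fell, are not on this list. INSM1 and SPDEF are also in fixed lists whose medians had been seen, and without them the median of the other 26 genes was 0.30, again above all random lists (highest 0.21), a check added after the result was seen. A general rise of tissue-restricted genes may account for part of this: of 3 comparison lists 1 passed the 95% bound (absorptive gut genes, median 0.19, 96.9%), with neuronal genes at 0.17 (94.96%) and skeletal muscle genes at 0.16 (93.3%). The secretory median was the highest of the 4, but the lists were not tested against each other, so both explanations stay open.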
